A study of Homo sapiens with 6 samples.

How the data were processed

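Total RNA of HCT116 cells was extracted with Trizol and purified on columns, and biotin-labelled cRNA was hybridised to Illumina expression arrays, per the labels' protocols. The labels give 3 groups of 2 arrays, and both the group and the replicate number were taken from them. The deposited non-normalized table holds, for 47323 probes and each of the 6 arrays, a mean signal as an intensity on a linear scale and a detection p-value, which is the share of negative control beads at least as bright. The highest intensity of an array lay between 22579 and 24779 and the median between 102 and 109. Each array's detection p-values fell in step with its own signals on all 6 arrays and with those of no other array. The deposited series table holds log2 values made by the authors with lumi, per the submitters' processing notes, which give no version. Its values rank the probes of each array exactly as the signal does (largest rank difference 0), its column medians are 6.75 on every array, and its sorted columns differ by at most 0.000672, so its scale is log2 and its columns are quantile normalized by their values. Which background step, if any, preceded it is not given in the sources used here.

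Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3. It fits a normal background, with its mean and spread inferred from the detection p-values, and an exponential signal, adds an offset of 16, applies quantile normalization and takes log2. Because the background is subtracted and an offset added, folds of dim genes are understated and depend on the offset. A probe was kept if its detection p was under 0.05 on both arrays of at least 1 group, which left 19781 probes. Gene names came from the platform annotation of the probes: 30113 probes had 1 gene symbol, 8 had several and 17202 were not listed. Symbols were compared through gene identifiers with a RefSeq table of assembly GRCh38.p14, used for names only, and 0 needed an update. Each gene was represented by its kept probe with the highest mean over the 6 arrays, chosen without regard to groups, and 3033 genes had more than 1 kept probe. Probes without a single symbol stayed as rows of their own.

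One linear model with a mean for each group was fitted to all 6 arrays, so that the 3 groups shared 1 estimate of the spread with 3 residual degrees of freedom. Moderation with eBayes added 4.54 prior degrees of freedom. The contrasts were each PEA15 shRNA against NS shRNA and shRNA 2 against shRNA 1, each two-sided and adjusted by the Benjamini-Hochberg method over all 15967 rows, with a threshold of 0.05. Errors beside log2 changes are limma's standard errors, and confidence intervals are at 95%. A gene not detected on either array of a group has only a bound there: the mean of the brighter group was set against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value of any detected probe on that array. Gene lists (29, each with at least 5 tested members) were compared with all other rows by camera with a preset correlation between genes of 0.01 and adjusted over the lists. With a correlation estimated from the 6 arrays the camera test has only 3 residual degrees of freedom, and no list passed in any comparison. The estimate was below the preset 0.01 for most lists. It was above it, at 0.044 and 0.098, for the lists of ATF4 and amino acid response genes and of heat shock genes. The preset test therefore allows for less correlation in these lists than was estimated. Lists share some genes.

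The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names PEA15, CDK6 and JUN. For each hairpin against the control it adds the 10 largest rises and 10 largest falls among genes past the threshold whose arrays lie on one side of both control arrays, for both hairpins up to 12 each way, and between hairpins 6 each way. For each list described it adds up to 4 members with the smallest adjusted p. The ATF4 list members ASNS, SLC7A11, SLC3A2, SLC7A5, GARS1 and ATF4 with shRNA 2, and the changes against the control of PKIB and KATNAL1 and of ADAM19 with shRNA 1, were named after their values were seen.

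The scripts were tested on simulated data drawn around the real means with each row's moderated spread, with 67 rows changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold among 15967. For shRNA 1 against NS shRNA 65.7% of rows changed by 1.5-fold, 100% of those changed by 2-fold and 100% of those changed by 4-fold were recovered. For shRNA 2 these shares were 67.2%, 98.5% and 100%, and between hairpins 59.7%, 100% and 100%. Unchanged rows called in error numbered 13, 11 and 14. These shares hold for the simulated rows only and are not the power of the real comparisons. With shRNA 1 the real changes of PKIB (1.03) and SCARNA8 (1.22) did not pass (limma adjusted p = 0.122 and 0.071). A list shifted in simulation was called in each of the 3 comparisons, with 0 other lists called. Rows were drawn independently of each other, so this cannot tell how often lists of correlated genes are called in error. Unchanged groups against shared controls were simulated 100 times in the same way. The split of the controls, with each hairpin's mean set against 1 NS array and in both orders, was added after the data were seen and simulated 100 times too.

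The alternatives were quantile normalization of log2 signals without background correction, median scaling, the submitters' processed values, an offset of 50, no detection filter, a detection p under 0.01 on all 6 arrays, every probe tested, the mean of the probes of a gene, eBayes with trend and robust options, array weights, only the 2 groups compared, the replicate number as a block, stricter thresholds, an estimated correlation, and leaving out each array. The contrast of the mean of both hairpins with the control was added after the data were seen. When an array was left out, normalization and rows stayed as they were and the lone array of that group was assumed to vary like the others. The files give no slide, position, scan date or culture, so such batches could not be checked. The 2 arrays of a group did not hold identical values, since they differed with an SD of 0.213 to 0.222 on the log2 scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.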

Results

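Gene expression was measured in HCT116, a human colorectal carcinoma cell line, after stable expression of short hairpin RNAs (shRNAs), which cells process into small RNAs that lower the matching messenger RNA. PEA15 encodes a small death effector domain protein that binds the kinases ERK1 and ERK2 and the adaptor FADD. The 6 samples formed 3 groups of 2: cells with a non-silencing hairpin (NS shRNA), with PEA15 shRNA 1 and with PEA15 shRNA 2. Each sample was hybridised to an Illumina expression array, on which bead-bound oligonucleotide probes capture labelled RNA. Each array gave 47323 probe signals, of which between 19441 and 20351 (41.1% to 43.0%) were detected above background. The tests covered 15967 rows, made up of 11498 genes and 4469 probes without a listed gene. Levels of the 2 arrays of a group correlated with r = 0.995 across rows in each group, and arrays of different groups with r from 0.989 to 0.994. The labels number the replicates but do not say that they were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical, and 2 arrays a group limit the precision. The series title places the study in the DNA damage checkpoint of the cell cycle and in transformation by oncogenes, so lists of such genes were fixed for every comparison.

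The targeted gene was lower on all 4 PEA15 shRNA arrays than on both control arrays. The log2 level of PEA15 was 8.97 and 9.15 on the NS arrays, 8.22 and 8.17 with shRNA 1, and 7.71 and 7.93 with shRNA 2. With shRNA 2 it fell by 1.23 ± 0.12 (log2, SE, n = 2 arrays a group) to 0.425 of the control level (95% confidence interval 0.350 to 0.516, limma adjusted p = 0.00573). With shRNA 1 the change was -0.86 ± 0.12, a ratio of 0.552 (95% confidence interval 0.455 to 0.670), which did not pass the genome-wide test (adjusted p = 0.122). The levels with the 2 hairpins differed by -0.38 (adjusted p = 0.122), which did not pass either. The shRNA 2 call was lost without NS shRNA replicate 2 (-1.14, adjusted p = 0.0745) and without PEA15 shRNA 2 replicate 1 (-1.12, adjusted p = 0.0592), against a range of 1.2e-07 to 0.0745 over its 18 alternatives. The shRNA 1 change passed under 5 of 18 alternatives, with adjusted p from 0.000182 to 0.427.

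**Figure D1:**
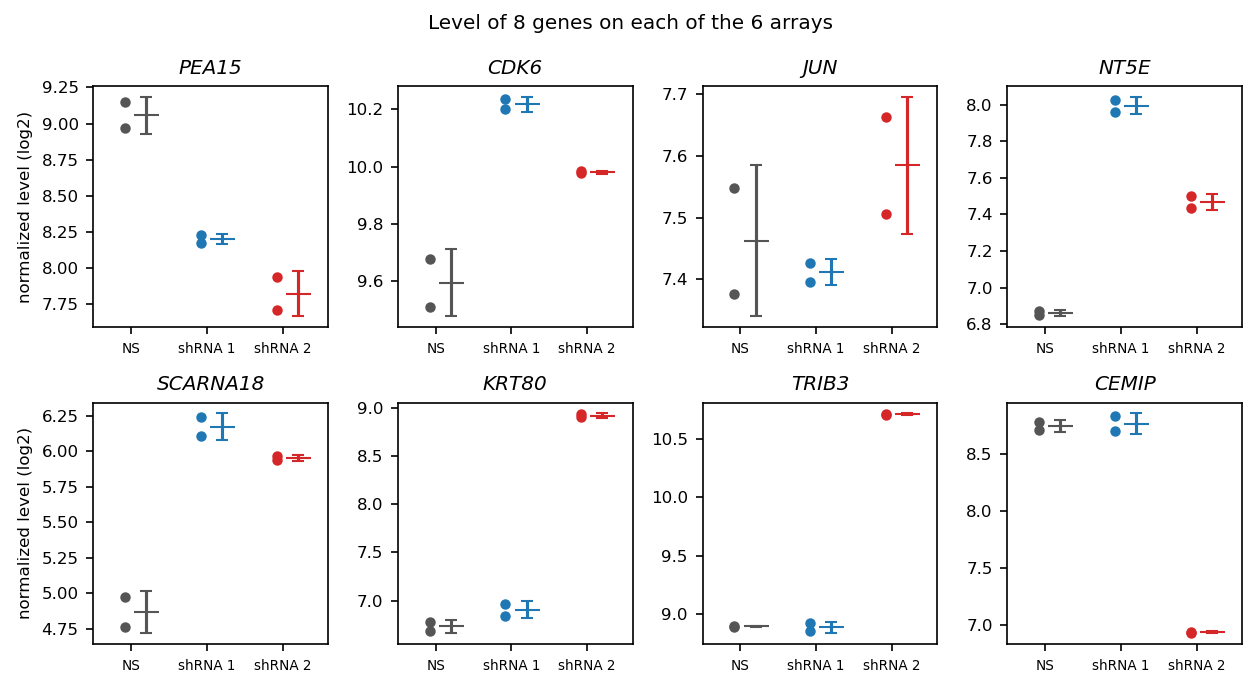
Normalized log2 level (y axis, a separate range for each gene) of 8 genes on the 6 arrays, by hairpin group (x axis). Points are single arrays, and the horizontal marks with bars are the mean and SD of the 2 arrays of a group. PEA15 lay between 7.71 and 8.22 on the PEA15 shRNA arrays and at 8.97 and 9.15 on the NS arrays, and TRIB3 and KRT80 stood apart on the shRNA 2 arrays.

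The first comparison asked what PEA15 shRNA 1 changed against the non-silencing hairpin. NT5E, which encodes the cell surface enzyme CD73 that makes adenosine from AMP, rose by 1.13 ± 0.10, a 2.20-fold difference (adjusted p = 0.0379, n = 2 arrays a group). SCARNA18, a small Cajal body RNA of the class that guides modification of spliceosomal RNAs, rose by 1.30 ± 0.11, or 2.47-fold (adjusted p = 0.0379), and was detected on 1 of the 2 NS arrays. CDK6, the cyclin D-dependent kinase of the G1 phase, stood at 10.24 and 10.20 on the shRNA 1 arrays against 9.51 and 9.68 on the NS arrays. Its change of 0.62 ± 0.10 did not pass the test over all rows (adjusted p = 0.159) and passed when adjusted over the list alone (adjusted p = 0.00943 in the list of cyclins, CDKs and their regulators). Over all rows it passed under 4 of 18 alternatives (adjusted p from 0.000388 to 0.451): quantile normalization alone, the submitters' processed values, a larger offset and a trended prior. JUN, a subunit of the AP-1 transcription factor, differed by -0.05 ± 0.11 (adjusted p = 0.903). PKIB, an inhibitor of protein kinase A, was 1.03 ± 0.14 higher without passing (adjusted p = 0.122). In all, 3 of 15967 rows changed, all higher, the last one being a probe without a listed gene (1.35). An unadjusted p under 0.05 was reached by 1873 rows, against 798 expected by chance, and the arrays of the 2 groups did not overlap for 42.2% of rows, against 33.3% by chance. The count was 162 (82 higher and 80 lower) with the submitters' processed values, 148 (73 and 75) with quantile normalization alone, 79 with a larger offset and 150 with a trended prior, each holding those 3 rows, and 29 with the stricter detection filter. With the replicate number as a block the count was 0 (limma, unadjusted p under 0.05 for 1927 rows). It was 0 without a detection filter, with only the 2 groups compared, and without any 1 of the 6 arrays (limma, unadjusted p under 0.05 for 1441 to 2945 rows).

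Of the 29 fixed gene lists, 3 moved with shRNA 1, all upward, while none of their members passed the test over all rows. The list of mesenchymal and invasion genes had a median change of 0.24, with 14 of 16 members above 0 (camera adjusted p = 4.6e-05, and adjusted p = 0.411 with an estimated correlation). Adjusted over the list alone, 2 of its members passed: MMP7, a secreted metalloproteinase, at 0.55 ± 0.10 and TGFBI, an extracellular matrix protein not detected on either NS array, at least 1.48-fold higher. The matricellular growth factors CCN2 and CCN1 were at 0.46 ± 0.14 and 0.31 ± 0.11. A dimmer MMP7 probe gave 1.30 and a dimmer CCN2 probe gave 0.0018. The list of ERK pathway output genes had a median of 0.16, with 19 of 25 members above 0 (adjusted p = 0.00668, and 0.434 as the adjusted p with an estimated correlation). Its leading members were the growth factor TGFA (0.43 ± 0.10), the receptor EPHA2 (0.42 ± 0.11), the AP-1 subunit FOSL1 (0.38 ± 0.11) and CCND1, or cyclin D1 (0.30 ± 0.10), and 0 passed when adjusted over the list alone. The p53 target list had a median of 0.08, with 20 of 29 members above 0 (adjusted p = 0.0376, and adjusted p = 0.454 with an estimated correlation). Its repair gene DDB2 (0.38 ± 0.09), the metabolic regulator TIGAR (0.32 ± 0.11), CDKN1A, which encodes the CDK inhibitor p21 (0.35 ± 0.12), and the stress protein SESN2 (0.38 ± 0.13) led it, and 0 passed when adjusted over the list alone. A second CDKN1A probe gave 0.95. The ERK call was lost without NS shRNA replicate 2 (adjusted p = 0.0776, range 0.000402 to 0.0776 over 18 alternatives), and the p53 call without NS shRNA replicate 1, NS shRNA replicate 2 or PEA15 shRNA 1 replicate 2 (adjusted p = 0.0837, 0.199 and 0.183, range 0.00607 to 0.199).

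PEA15 shRNA 2 changed 271 rows against the non-silencing hairpin, of which 192 were higher (141 named genes) and 79 lower (70 named genes). KRT80, an epithelial keratin, rose by 2.19 ± 0.10 (4.57-fold, adjusted p = 0.000384, n = 2 arrays a group). CHAC1, a glutathione-degrading enzyme, was at least 3.13-fold higher (adjusted p = 0.000384). The mitochondrial enzyme PCK2 rose by 1.90 ± 0.13 (3.73-fold, adjusted p = 0.00131), and the pseudokinase TRIB3 by 1.82 ± 0.09 (3.53-fold, adjusted p = 0.000526). The stress transcription factors ATF3 and DDIT3, also named CHOP, rose by 1.80 ± 0.10 and 1.63 ± 0.12, and PSAT1, an enzyme of serine synthesis, by 1.62 ± 0.10. The kinase ALPK2 was at least 2.85-fold higher, the hexokinase-related HKDC1 rose by 1.65 ± 0.17, and TNFSF18, a ligand of the tumour necrosis factor family, by 1.63 ± 0.15. CHAC1 and ALPK2 were not detected on either NS array, so their folds are bounds set from the lowest detected signal of those arrays.

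Among the genes lower with shRNA 2, CEMIP, a protein of hyaluronan breakdown, fell by 1.80 ± 0.10 (3.48-fold, adjusted p = 0.000591, n = 2 arrays a group). The membrane protease ADAM19 fell by 1.33 ± 0.11 (adjusted p = 0.00224), the growth factor FGF9 by 1.33 ± 0.10 (adjusted p = 0.0021) and the RNA-binding RBMS1 by 1.13 ± 0.11. The fall of ZCCHC12 was 1.11 ± 0.12. HSPA1B, an inducible HSP70 chaperone with a near-identical neighbour, HSPA1A, whose RNA its probe may also capture, fell by 1.08 ± 0.10. Not detected on either shRNA 2 array were RGS4, a regulator of G protein signalling (at least 1.83-fold lower), the epithelial transcription factor ELF5 (at least 2.10-fold lower) and the tight junction protein CLDN2 (at least 1.56-fold lower). Other probes of some of these genes read smaller changes: 0.79 for KRT80, 0.50 for PCK2, -0.14 for FGF9, and -0.05 and -0.26 for RBMS1. Another PCK2 probe gave 1.90. A change of at least 1 on the log2 scale was shown by 53 rows, 41 of them higher, and the arrays did not overlap for 50.1% of rows, against 33.3% by chance. The count was 1004 (554 higher and 450 lower) with the submitters' processed values, 1003 (545 and 458) with quantile normalization alone, 829 (474 and 355) with a larger offset, 942 with a trended prior, 592 (346 and 246) with the stricter detection filter, 116 with no detection filter and 165 with only the 2 groups compared. It was 25 without NS shRNA replicate 1, 20 without NS shRNA replicate 2, 165 without either PEA15 shRNA 1 array, 17 without PEA15 shRNA 2 replicate 1 and 25 without PEA15 shRNA 2 replicate 2.

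With shRNA 2, genes of the ATF4 and amino acid response rose together. ATF4 is a transcription factor made when amino acids are scarce or the endoplasmic reticulum is stressed. Of the 22 members tested, 16 rose, 0 fell and 6 did not pass over all rows, and 22 passed when adjusted over the list alone. The median change was 0.93, with an SD of 0.53 over members and 22 of 22 above 0 (camera adjusted p = 4.2e-32, and adjusted p = 0.0691 with an estimated correlation). Besides CHAC1, TRIB3, ATF3, DDIT3 and PSAT1, the asparagine synthetase ASNS rose by 1.59 ± 0.10 (3.02-fold, adjusted p = 0.000885). The cystine transporter subunits SLC7A11 and SLC3A2 rose 2.83-fold (adjusted p = 0.00674) and by 1.09 ± 0.10, the leucine transporter SLC7A5 by 0.80 ± 0.10, the glycyl-tRNA synthetase GARS1 by 0.80 ± 0.09 and ATF4 itself by 0.85 ± 0.10. In the shRNA 1 comparison the median of this list was -0.05, with 8 of 22 members above 0 and 0 past the test (camera adjusted p = 0.672). The list of endoplasmic reticulum chaperone genes did not pass: its median with shRNA 2 was -0.11, with 4 of 19 members above 0 (adjusted p = 0.151), and with shRNA 1 it was -0.02 (adjusted p = 0.796). Its member XBP1, a transcription factor of endoplasmic reticulum stress, was at 0.46 ± 0.11 with shRNA 2 without passing (adjusted p = 0.0833). XBP1 was 0.65 ± 0.11 higher with shRNA 2 than with shRNA 1, past the test (adjusted p = 0.0254), and its other probe gave 0.64 and 0.93.

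**Figure D2:**
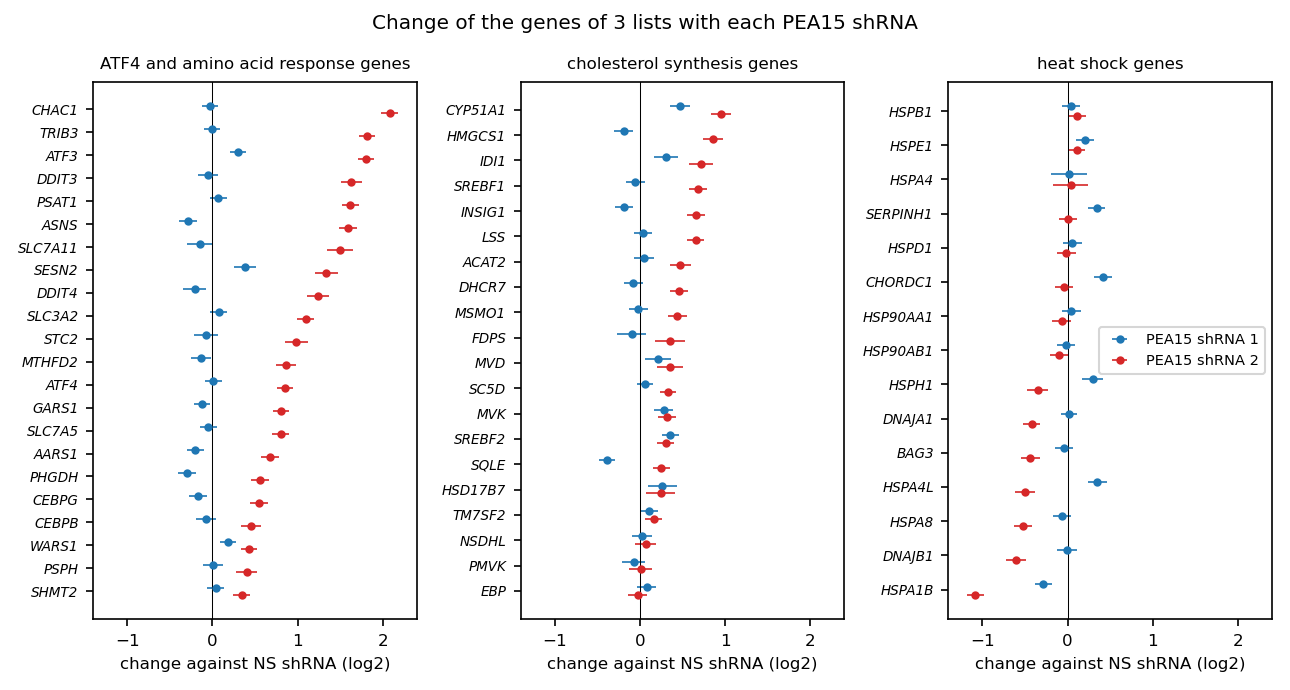
Change against the NS shRNA arrays (x axis, log2) of each tested gene (y axis) of 3 lists, with shRNA 1 in blue and shRNA 2 in red. Points are limma estimates and bars their SE, from 2 arrays a group. All 22 ATF4 and amino acid response genes lie above 0 with shRNA 2, with a median of 0.93, against a median of -0.05 with shRNA 1.

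Cholesterol synthesis genes also moved up with shRNA 2. Of 20 tested, 5 rose and 0 fell, 13 passed when adjusted over the list alone, and 19 lay above 0, with a median of 0.35 (adjusted p = 3.9e-10, and adjusted p = 0.0778 with an estimated correlation). The sterol demethylase CYP51A1 rose by 0.95 ± 0.12, the synthase HMGCS1 by 0.85 ± 0.12, the sterol-sensing regulator INSIG1 by 0.66 ± 0.10 and SREBF1, a transcription factor of lipid synthesis, by 0.69 ± 0.11. Interferon response genes had a median of 0.18, with 1 of 29 past the test over all rows, 7 when adjusted over the list alone and 24 above 0 (adjusted p = 0.000283, and adjusted p = 0.221 with an estimated correlation). The called member was IFI27, which rose by 0.86 ± 0.11, and IFI6 (0.52 ± 0.11), SAMD9 (0.52 ± 0.11) and IRF9 (0.40 ± 0.09) followed without passing over all rows. Of 29 p53 target genes, 2 rose over all rows and 6 passed when adjusted over the list alone, with a median of 0.21 (adjusted p = 0.000932, and adjusted p = 0.219 with an estimated correlation). These 2 were SESN2, at 1.34 ± 0.13, also a member of the ATF4 list, and the secreted stress factor GDF15, at 1.11 ± 0.13, and both are known to respond to ATF4 as well as to p53. CDKN1A was at 0.20, without passing.

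Mesenchymal and invasion genes moved up with shRNA 2 too, with 5 of 16 past the test over all rows and adjusted over the list alone, a median of 0.07 and a mean of 0.23 (adjusted p = 0.0285, and adjusted p = 0.221 with an estimated correlation). The receptor kinase AXL rose by 0.86 ± 0.12, CCN1 by 0.78 ± 0.11, the urokinase PLAU by 0.78 ± 0.12 and the matrix protein THBS1 by 0.86 ± 0.14, while MMP7 was at -0.28, with its dimmer probe at 0.18. NF-kB target genes had a median of 0.20 with 0 of 9 past the test over all rows and 2 when adjusted over the list alone (adjusted p = 0.0115, and adjusted p = 0.221 with an estimated correlation), led by NFKB2 (0.50 ± 0.11) and TNFAIP2 (0.39 ± 0.11). Replication-dependent histone genes had a median of 0.25 with 0 of 9 past over all rows and 1, H2AC6 (0.53 ± 0.13), when adjusted over the list alone (adjusted p = 0.0136, and adjusted p = 0.221 with an estimated correlation). These 3 calls were lost without PEA15 shRNA 2 replicate 2 (adjusted p = 0.0637, 0.0639 and 0.0636), the mesenchymal and NF-kB calls also without NS shRNA replicate 2 (adjusted p = 0.0843 and 0.0752). The mesenchymal call was also lost with every probe tested (0.072) and with no detection filter (0.0502), and the histone call with the stricter filter (0.0571). Over 18 alternatives the adjusted p ranged from 0.00465 to 0.0843 for mesenchymal, 0.000495 to 0.0752 for NF-kB and 0.00719 to 0.0636 for histone genes.

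Of the lists that moved down with shRNA 2, Wnt target genes had the lowest median, -0.24, with 2 of 15 lower and 0 higher over all rows, and 4 lower and 2 higher when adjusted over the list alone (adjusted p = 0.00437, and adjusted p = 0.221 with an estimated correlation). AXIN2 and NOTUM, both feedback inhibitors of Wnt signalling, fell by 1.04 ± 0.11 and 0.77 ± 0.13, and ZNRF3 (-0.54 ± 0.11) and SP5 (-0.57 ± 0.13) followed without passing. Heat shock genes had a median of -0.10 and a mean of -0.26, with HSPA1B the 1 of 15 that fell over all rows and 7 lower when adjusted over the list alone (adjusted p = 0.00169, and adjusted p = 0.221 with an estimated correlation). The co-chaperone DNAJB1 was at -0.60 ± 0.12 and the constitutive chaperone HSPA8 at -0.52 ± 0.10. The list of G1/S and DNA replication genes, which the study's subject makes of interest, had a median of -0.12, with 28 of 39 members below 0 and 0 past the test over all rows or adjusted over the list alone (adjusted p = 0.0204, and adjusted p = 0.221 with an estimated correlation). Its leading members were the flap endonuclease FEN1 (-0.39 ± 0.10), the replication factor GINS3 (-0.37 ± 0.10) and CCNE1, or cyclin E1 (-0.40 ± 0.12). The G1/S call was lost without NS shRNA replicate 1 (adjusted p = 0.0501) and without PEA15 shRNA 2 replicate 2 (adjusted p = 0.0677), against a range of 0.00342 to 0.0677 over 18 alternatives.

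**Figure D3:**
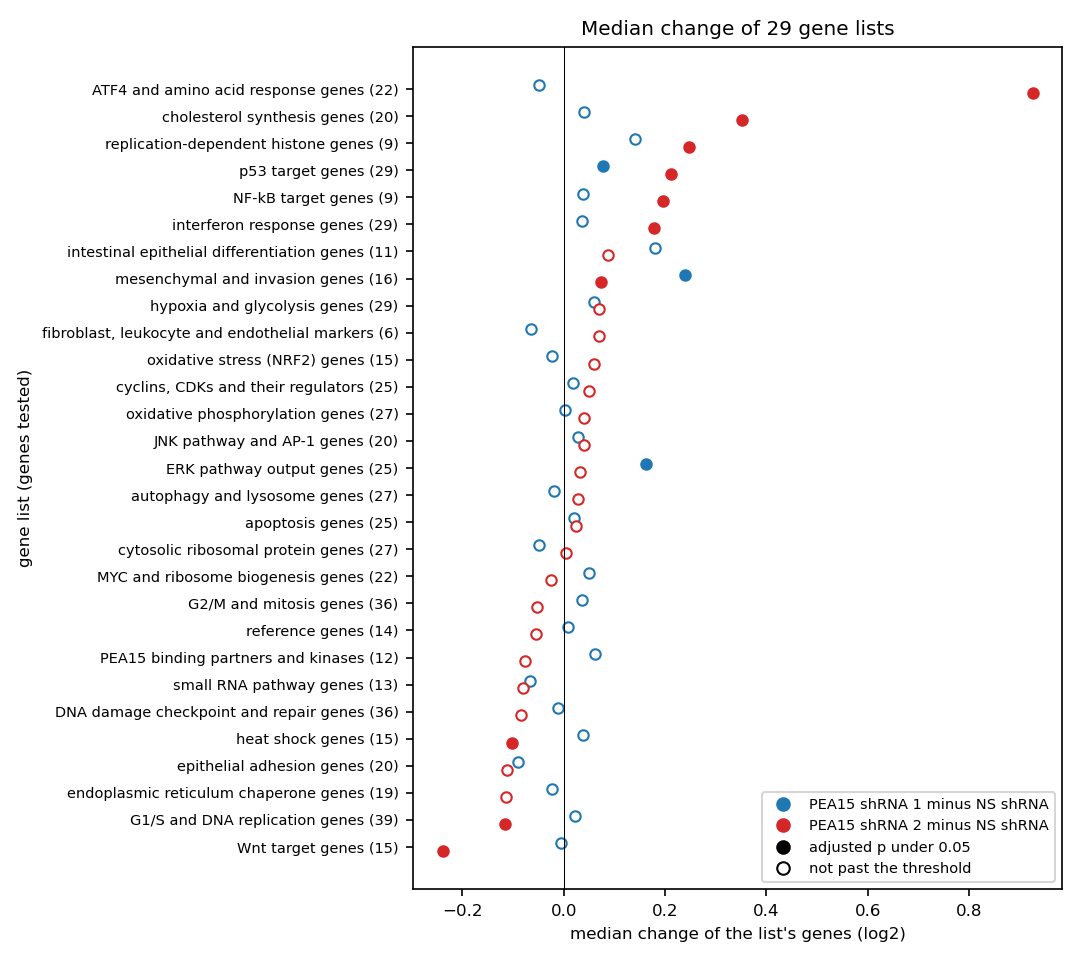
Median log2 change (x axis) of the tested genes of each of 29 lists (y axis, number of genes tested in brackets) with shRNA 1 in blue and shRNA 2 in red against NS shRNA. Filled points passed camera's test at a preset correlation and open points did not. The ATF4 and amino acid response list lies at 0.93 with shRNA 2 and at -0.05 with shRNA 1.

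The other 18 lists passed with neither hairpin. Among them were 3 lists of the cell cycle and the DNA damage response. Others of that kind had passed: p53 target genes with both hairpins, and G1/S and DNA replication genes with shRNA 2. G2/M and mitosis genes had medians of 0.04 with shRNA 1 and -0.05 with shRNA 2 over 36 genes, and DNA damage checkpoint and repair genes -0.01 and -0.08 over 36 genes. Cyclins, CDKs and their regulators had medians of 0.02 and 0.05 over 25 genes. With shRNA 2 the phosphatase CDC25A, an activator of CDKs, was at -0.52 ± 0.10 (adjusted p = 0.0516), CDK6 at 0.39 ± 0.10 (adjusted p = 0.111) and JUN at 0.12 ± 0.11 (adjusted p = 0.612). CDK6 passed with shRNA 2 under the same 4 of 18 alternatives as with shRNA 1 (adjusted p from 0.00553 to 0.342), and JUN under 0 of 18 with either hairpin (smallest adjusted p = 0.516). Medians with shRNA 1 and shRNA 2 were 0.03 and 0.04 for JNK pathway and AP-1 genes, 0.06 and -0.08 for PEA15 binding partners and kinases, 0.02 and 0.02 for apoptosis genes, and -0.02 and 0.03 for autophagy and lysosome genes. They were 0.06 and 0.07 for hypoxia and glycolysis genes, 0.00 and 0.04 for oxidative phosphorylation genes, 0.05 and -0.03 for MYC and ribosome biogenesis genes, and -0.09 and -0.11 for epithelial adhesion genes. For intestinal epithelial differentiation genes they were 0.18 and 0.09, for NRF2 oxidative stress genes -0.02 and 0.06, for small RNA pathway genes -0.07 and -0.08, for cytosolic ribosomal protein genes -0.05 and 0.01, and for reference genes 0.01 and -0.06. Markers of fibroblasts, leukocytes and endothelium, of which 6 of 22 were tested, were at -0.07 and 0.07, and ACTA2, a smooth muscle actin in that list, was at 0.63 ± 0.10 and 0.46 ± 0.10 without passing over all rows. Adjusted over the list alone, ACTA2 passed with both hairpins. In the other lists that did not pass, the members past when adjusted over the list alone with shRNA 1 were 1 of the cyclin list (CDK6), 1 of NF-kB genes (CXCL8, 0.60), 1 higher and 1 lower of cholesterol synthesis genes, 1 of hypoxia and glycolysis genes (SLC2A1, 0.59), 1 lower of epithelial adhesion genes (GRHL2, -0.62) and 2 of histone genes. With shRNA 2 they were 1 lower of the cyclin list (CDC25A), 4 of ERK output, 4 of JNK and AP-1, 3 higher and 1 lower of apoptosis, 1 of autophagy and lysosome, 3 of hypoxia and glycolysis, 1 of MYC and ribosome biogenesis, 2 of epithelial adhesion, 3 higher and 1 lower of intestinal differentiation, and 2 higher and 1 lower of NRF2 genes. Single members of these lists rose with shRNA 2: the autophagy gene ATG12 by 1.06 ± 0.10, the glucose transporter SLC2A3 by 1.29 ± 0.15, the growth factor VEGFA by 0.88 ± 0.12, the transcription factor KLF4 by 1.17 ± 0.15 and the NRF2 target TXNRD1 by 0.77 ± 0.10. The ERK phosphatase DUSP5 rose by 0.86 ± 0.10 and EPHA2 by 0.83 ± 0.11, in an ERK output list whose median with shRNA 2 was 0.03 (adjusted p = 0.132). The proapoptotic BID fell by 0.53 ± 0.09, with other probes at -0.39 and 0.19, and the adhesion molecule CEACAM1 by 0.73 ± 0.11. The median, mean and test differed in sign for the interferon response, NF-kB, oxidative phosphorylation, Wnt and fibroblast, leukocyte and endothelial lists with shRNA 1, for the ribosomal protein list with shRNA 2, and for the apoptosis and the fibroblast, leukocyte and endothelial lists between hairpins.

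Both hairpins were then set side by side, to see which changes did not depend on 1 hairpin. NT5E and SCARNA18 rose with both: NT5E by 1.13 ± 0.10 and 0.61 ± 0.10, and SCARNA18 by 1.30 ± 0.11 and 1.08 ± 0.11, with shRNA 1 and shRNA 2 (n = 2 arrays a group). These were 2 of 15967 rows, both higher and 0 lower. Independent lists would share 0.0361 rows, a figure that leaves out the shared control arrays. In 100 simulations of unchanged groups that shared the controls the mean was 0. With no changed row in them, that count could hardly differ from 0. Neither figure tells how many called rows the shared controls alone would bring together. At an unadjusted p under 0.05 in one direction, 488 rows were shared, against 181 in the simulations (range 152 to 210). The log2 changes correlated with r = 0.278 across rows, which are not independent replicates, against 0.483 to 0.517 simulated, and their covariance was 0.0133 against 0.00903 (range 0.00861 to 0.00964). The simulations used the moderated spread and held no real change with either hairpin. The excess of shared rows and of covariance over them therefore cannot be read as agreement between the hairpins. With 1 control array for each hairpin, so that no array was shared, the covariance was 0.00224 and 0.00117 in the 2 orders, against -0.00067 to 0.000586 simulated. The changes then had one sign for 51.0% and 49.2% of rows, against 48.8% to 51.0% simulated. Most of the covariance with shared controls was therefore lost once they were split, and the split leaves in place whatever both control arrays have in common. With the submitters' processed values 37 rows were shared, with quantile normalization alone 33, with a larger offset 21, with a trended prior 35, with the stricter filter 11 and with the replicate number as a block 0. The count was 0 with no detection filter, with only the 2 groups compared and without any 1 of the 6 arrays.

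**Figure D4:**
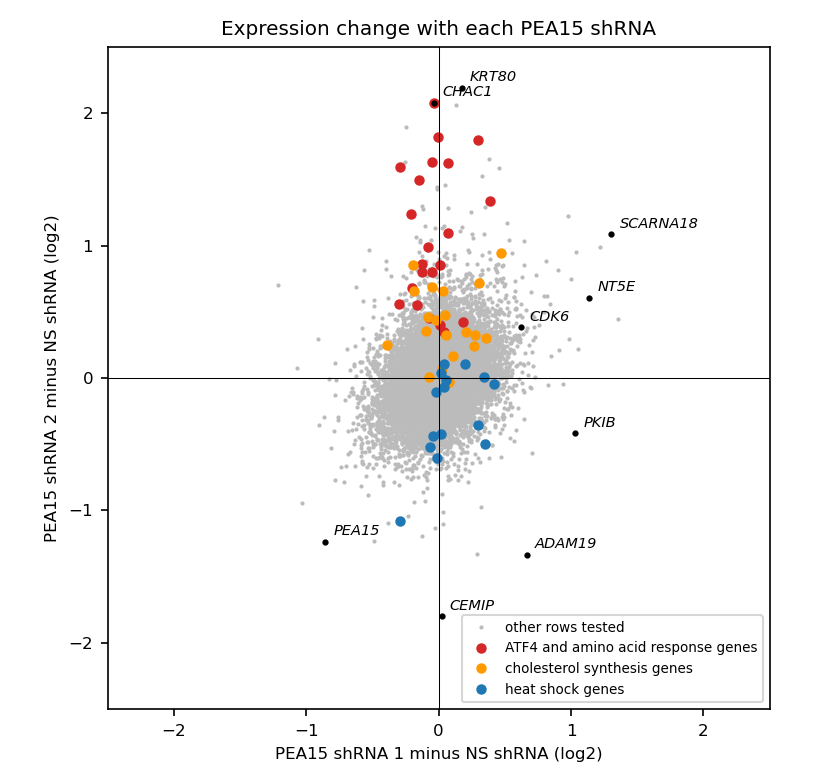
Log2 change of every row tested with shRNA 1 (x axis) and shRNA 2 (y axis) against the same 2 NS shRNA arrays, each point a gene or a probe without a listed gene. Members of 3 lists are coloured, and 9 genes are named. NT5E lies at 1.13 and 0.61 and PEA15 at -0.86 and -1.23, while the ATF4 and amino acid response genes spread along the y axis.

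The direct test between the hairpins does not use the levels of the control arrays, though they enter its estimate of the spread. With shRNA 2, PCK2 was higher than with shRNA 1 by 2.14 ± 0.13 (4.41-fold, adjusted p = 0.000766), KRT80 by 2.02 ± 0.10, TNFSF18 by 1.89 ± 0.15, ASNS by 1.88 ± 0.10 and TRIB3 by 1.82 ± 0.09, and CHAC1 was at least 3.11-fold higher (n = 2 arrays a group). Lower with shRNA 2 were ADAM19, by 2.00 ± 0.11 (4.00-fold lower, adjusted p = 0.000451), CEMIP, FGF9, PKIB, the hyaluronan synthase HAS3 and KATNAL1, which is related to a microtubule-severing enzyme. Other probes of these genes gave differences of 0.47 and 1.99 for PCK2, 1.11 for KRT80, 1.72 for ASNS, -0.30 for FGF9 and -1.30 for HAS3. ADAM19 was at 0.66 ± 0.11 with shRNA 1 and -1.33 ± 0.11 with shRNA 2, and KATNAL1 at 0.71 ± 0.11 and -0.57 ± 0.11, of which the ADAM19 fall with shRNA 2 passed against the controls. The test called 530 rows, 319 higher and 211 lower with shRNA 2. The arrays did not overlap for 53.7% of rows, against 33.3% by chance. Of the 29 lists, 4 were higher and 3 lower with shRNA 2, and 0 passed with an estimated correlation (camera, 5 at an unadjusted p under 0.05, smallest adjusted p = 0.0845). ATF4 and amino acid response genes differed by a median of 0.97, with 18 of 22 higher over all rows and 22 when adjusted over the list alone (adjusted p = 5.3e-28, and adjusted p = 0.0845 with an estimated correlation). Cholesterol synthesis genes differed by a median of 0.42 with 6 of 20 higher, interferon response genes by 0.20 with 3 of 29 higher, and NF-kB target genes by 0.27 with 0 of 9 past (adjusted p = 5.3e-06, 0.000545 and 0.0387). Adjusted over the list alone, 11, 8 and 3 of these were higher, and the adjusted p with an estimated correlation was 0.167, 0.26 and 0.356. Lower were heat shock genes, with a median of -0.40 and 4 of 15 lower, Wnt target genes, at -0.31 with 3 of 15 lower and 2 higher (LEF1 and MYC), and G1/S and DNA replication genes, at -0.06 with 1 of 39 lower, the replication factor GINS1 (adjusted p = 1.5e-05, 0.00324 and 0.0387). Adjusted over the list alone, 9, 7 and 6 of these were lower and 2 Wnt target genes higher, and the adjusted p with an estimated correlation was 0.26, 0.26 and 0.367. The NF-kB call was lost under 8 of 18 alternatives (adjusted p from 0.0144 to 0.158) and the G1/S call under 5 of 18 (adjusted p from 0.00688 to 0.112), in both cases without either PEA15 shRNA 1 array and without PEA15 shRNA 2 replicate 2. The row count was 1785 with the submitters' processed values, 1759 with quantile normalization alone, 1508 with a larger offset, 1722 with a trended prior, 1139 with the stricter filter, 247 with no filter and 230 with only the 2 groups compared or without either NS array. It was 56 and 89 without PEA15 shRNA 1 replicate 1 and replicate 2, and 35 and 54 without PEA15 shRNA 2 replicate 1 and replicate 2.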

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

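For the ATF4 pattern, the tests of grading with the PEA15 level, of normalization and of endoplasmic reticulum stress were chosen after the result was seen, and the test of tRNA synthetase genes before its result was seen. What singled these results out is a difference between the effects of the 2 hairpins by the direct test between them. That test called 530 rows. The lists it called differed by medians, shRNA 2 minus shRNA 1, of 0.97 for ATF4 and amino acid response genes, 0.42 for cholesterol synthesis genes, 0.27 for NF-kB target genes, 0.20 for interferon response genes, -0.40 for heat shock genes, -0.31 for Wnt target genes and -0.064 for G1/S and DNA replication genes. With an estimated correlation 0 of these lists passed (smallest adjusted p = 0.0845), and the NF-kB and G1/S calls were also lost under 8 and 5 of 18 alternatives.

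The rise of ATF4 and amino acid response genes with shRNA 2 was first set against the PEA15 level. The values argue against a response in proportion to the log2 change of PEA15, while a steeper grading was not tested. The PEA15 change with shRNA 1 was 0.695 of that with shRNA 2, which predicts a list median of 0.64 with shRNA 1. The median was -0.050 with a standard error of 0.046. This standard error, like that of the chaperone list median, is over genes, which are not independent replicates. It also leaves out the error of the PEA15 ratio. Background correction and normalization as the whole cause is argued against by a lowest median of 0.80 over 4 other normalizations, and stress of the endoplasmic reticulum that raises its chaperones by a median of -0.11 ± 0.06 (SE) for the chaperone list. XBP1, a member of that list, went the other way, at 0.46 with shRNA 2 and 0.65 between hairpins (adjusted p = 0.0833 and 0.0254), so a stress signal that leaves the chaperones unchanged stays open. A wider amino acid response is consistent with further cytosolic tRNA synthetase genes having higher changes than mitochondrial ones (permutation p = 0.00061). A response that needs PEA15 below a threshold, another target of hairpin 2, and a different culture state of the shRNA 2 samples may each account for the pattern, were not tested, and a culture or slide that coincides with the hairpin cannot be told apart from it.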

How the results depend on the processing

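Of the alternatives reported here, only the contrast of the mean of both hairpins with the control was chosen after the data were seen. The counts given in order are for shRNA 1, shRNA 2, the difference between hairpins and both hairpins in one direction, and were 3, 271, 530 and 2. They became 148, 1003, 1759 and 33 with quantile normalization without background correction, 162, 1004, 1785 and 37 with the submitters' processed values, and 79, 829, 1508 and 21 with an offset of 50. With a trended and robust prior they were 150, 942, 1722 and 35, and with a detection p under 0.01 on all 6 arrays 29, 592, 1139 and 11. They were 0, 116, 247 and 0 with no filter, where 37256 rows were tested, and 0, 165, 230 and 0 with only the 2 groups compared, which leaves fewer degrees of freedom. At an adjusted p under 0.01 they were 0, 53, 67 and 0, and with a log2 change of at least 1 the last 3 were 53, 64 and 1. Leaving out 1 array gave 0 to 0, 17 to 165, 35 to 230 and 0 to 0. The counts of 165 and 230 came from leaving out an array of the group not compared, as with only the 2 groups compared. The count for shRNA 1 was 0 in that case too. Counts for shRNA 2 and the difference were lower where a compared group was left as a single array. The mean of both hairpins against NS shRNA gave 20 rows with one sign, 10 of them resting mostly on 1 hairpin. The cause of the moves in these counts was not tested. Of the 271 rows called with shRNA 2, 247 were also called with the submitters' processed values and 261 with the trended prior, and median scaling, every probe, the mean of probes and array weights stayed within 1.5 times of every count. PEA15 with shRNA 1 passed at -0.71 with quantile normalization alone, -0.70 with the submitters' values, -0.79 with an offset of 50, and -0.86 with the stricter filter and with the trended prior, and ranged from -0.95 to -0.77 with 1 array left out. With shRNA 2 it ranged from -1.35 to -1.12 with 1 array left out. Deviations of same-numbered arrays correlated weakly, at -0.02, 0.05 and 0.08. The labels do not say whether same-numbered samples were processed together. With the replicate number as a block, the counts were 0, 142, 333 and 0 (limma, unadjusted p under 0.05 for 1927 rows with shRNA 1). Lists past camera's test numbered 3, 10 and 7 for shRNA 1, shRNA 2 and the difference, 0, 0 and 0 with an estimated correlation (3, 5 and 5 at an unadjusted p under 0.05), and 1 to 3, 6 to 11 and 5 to 7 with 1 array left out. Of the lists that passed, 0 turned direction under any alternative. Among 76 called changes of named genes, 842 of 901 values with all arrays kept stayed past the test and 59 lost it, and 225 of 456 stayed past with 1 array left out. Of 54 changes not past the test, 135 of 641 values passed with all arrays kept. Of these changes, 2 turned sign: DCLK1 with shRNA 1 to -0.087 with the mean of its probes, and JUN with shRNA 1, which ranged from -0.14 to 0.036 with 1 array left out, without NS shRNA replicate 2. Signal over background limits dim genes: 31 of the 271 changes with shRNA 2 are bounds only.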

Other observations

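The tests of further cytosolic synthetase genes, small RNAs, YAP and TEAD targets and the p53 list were written before their results were seen, on patterns noticed in the same data. The contrast of the mean of both hairpins was chosen after the data were seen, and the genes named in this part after their values were seen. Genes of cytosolic aminoacyl-tRNA synthetases, the enzymes that charge tRNAs for translation, were compared with mitochondrial ones beyond the 4 that the ATF4 list holds, and were not tested as a list against the control. Of 15 other cytosolic ones tested singly with shRNA 2, 3 rose, YARS1 by 0.73 ± 0.10, MARS1 by 0.62 ± 0.10 and SARS1 by 0.59 ± 0.10 (log2, SE), and 11 lay above 0 and 4 below, with a median of 0.27. The 15 mitochondrial synthetase genes had a median of -0.09, with 4 above 0 and 0 past the test. The medians differed by 0.36 (two-sided permutation p = 0.00061 over 100000 resamples of genes, which are not independent replicates). With shRNA 1 the medians were 0.03 and -0.05.

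Small Cajal body RNAs were looked at as a class after SCARNA18 and SCARNA8 were seen, and were not tested as a list. Of 10 tested singly, these 2 included, 1 passed the test over all rows with shRNA 1 and 3 with shRNA 2, while 9 and 10 lay above 0, with medians of 0.82 and 0.53. SCARNA8 was at 1.22 ± 0.13 with shRNA 1 (adjusted p = 0.071) and rose by 0.99 ± 0.13 with shRNA 2, and SCARNA13 rose by 0.76 ± 0.10 with shRNA 2. Tested against the control as the mean of both hairpins, a contrast added after the data were seen, 20 rows with one sign changed, 14 higher and 6 lower. In 10 of the 20 the larger change was more than 2 times the smaller, in 9 of these with shRNA 2, as for PSAT1 (1.62 against 0.07) and KRT80 (2.19 against 0.17), so they rest mostly on 1 hairpin. Among the others were PEA15 (-1.05 ± 0.10, adjusted p = 0.0157), DDIT4L, an inhibitor of mTOR signalling (-0.78 ± 0.09), the ectodysplasin receptor EDAR, not detected with either PEA15 hairpin and at least 1.49-fold lower with each, and the kinase DCLK1 (0.75 ± 0.09). DCLK1 rests on its brightest probe: with the mean of its probes it was at -0.087 with shRNA 1 and 0.37 with shRNA 2, neither past the test (adjusted p = 0.836 and 0.167). CDK6, at 0.51 ± 0.09, did not pass (adjusted p = 0.106). All 4 PEA15 shRNA arrays lay on one side of both NS arrays for 16.2% of rows, against 13.3% by chance.

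A greater recovery of small RNAs in the PEA15 shRNA samples could raise SCARNA18 and SCARNA8. Over all 156 small RNA genes tested, the median of the mean change over both hairpins was 0.042 ± 0.026 (SE over genes, which are not independent replicates). That median is below the 0.5 set for that explanation, which argues against it for the class as a whole, although 98 of the 156 lay above 0. A median over the class cannot tell whether some small RNAs only were recovered better, and this was not tested. Normalization was left unsettled, as the smaller mean change of the 2 genes was 0.43 at its lowest over 4 other normalizations, between the bounds set for either outcome. An effect of the lower PEA15 level, and a state of the 2 control samples that both comparisons share, stay open and were not tested.

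A hypothesis from NT5E, CCN1, CCN2 and AXL, known targets of the transcription regulators YAP and TEAD, is that this programme may be higher with both hairpins. Of these genes NT5E alone passed the test over all rows with shRNA 1. CCN2 was at 0.46 with shRNA 1 and 0.75 with shRNA 2, while its dimmer probe gave 0.0018 and 0.26. Of 18 other targets 13 were tested, among them GADD45A, whose shRNA 2 value had been seen in the p53 list, with medians of 0.07 with shRNA 1 (camera p = 0.104) and 0.31 with shRNA 2 (camera p = 0.000447, and p = 0.0339 with an estimated correlation), and 0 passed the test over all rows with either hairpin. The test had asked for a rise with both hairpins, so it left the hypothesis unsettled: the 13 moved up with shRNA 2 and did not pass with shRNA 1. Of the 13, 9 lay above 0 with shRNA 1 and 10 with shRNA 2. That the p53 list moved with shRNA 2 through SESN2 and GDF15 alone is argued against by the 27 other members, whose median was 0.21 with 21 above 0 (camera p = 0.00274, and p = 0.0436 with an estimated correlation, neither adjusted over lists). SESN2 and GDF15 were the only members past the test over all rows. Whether the other members rose through p53 or through ATF4 was not tested.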
